A study of Escherichia coli with 17 samples.

How the data were processed

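Transcripts of Escherichia coli were measured on membrane macroarrays hybridized with radiolabelled cDNA made from total RNA. Per the labels, 17 treatments were compared with untreated controls: 13 single drugs, 3 drug pairs and the lac operon inducer IPTG. Each treatment had 2 replicates, and each replicate a treated and a control membrane, so the series held 68 membranes. Doses, exposure times, medium and strain are not given in the sources used here. Nothing in the labels says that the replicates came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

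The deposited spot intensities were volumes of duplicate spots for 4290 features per membrane. Per the series design text they had been background-corrected by the authors, and 0% to 3.85% of the spots per membrane lay below 0. The image software is not given in the sources used here. The intensities had not been scaled between membranes, since their totals ran from 9.89e+06 to 1.15e+08 volume units per membrane. Treated and control columns were told apart by their names, and the reading was checked against the sign of the deposited score. The second kind of value was the authors' deposited score, the relative volume difference. Per the design text it is the treated minus control volume after scaling to total intensity, averaged over both replicates and divided by an error estimate, with values at or past 2 or -2 taken as changed. The formula of that error estimate is not given in the sources used here, so the score has no stated scale beyond its threshold. Its median over genes ran from -0.09 to 0.18 across treatments, and its direction is treated minus control. In 16 treatments the score ranked genes like the volume difference recomputed from the intensities, with Spearman rho from 0.963 to 0.986. Under chloramphenicol rho was 0.362, so that treatment's score and intensities do not match and its values carry this doubt throughout.

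Gene symbols were those of the platform annotation given with the score table, and 4094 of the 4290 features matched a locus of the RefSeq annotation of assembly ASM584v2, which was used for names and not for coordinates. A symbol was present for 4095 features and absent for 195, and 0 features had several. All columns of per-sample values were assigned to a treatment.

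From the intensities, duplicate spots were averaged, each membrane was scaled to its mean volume, values under 0.1 of that mean were set to this floor, and the log2 ratio of treated over control was taken per replicate. A ratio with both sides at the floor was left out. A gene was tested in a treatment where both replicates gave a ratio, a rule settled after the data had been examined. The 34 columns of log2 ratios went into 1 limma fit with 1 coefficient per treatment tested against 0, with 17 residual degrees of freedom and a prior of 4.54. The adjusted p is Benjamini-Hochberg within a treatment, with the threshold at 0.05. Because replicates spread more in some treatments than in others, a second limma fit gave each treatment 1 array weight. That fit was added after the data had been examined, and its calls are given beside the others. Errors of log2 ratios are the SE from the first fit (n = 2). They rest on the spread shared by all treatments, so a gene has the same SE wherever both replicates gave a ratio. For groS it was 0.54 under kanamycin and under paromomycin. They do not show how far the 2 replicates of that treatment lay apart. Computations used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and Matplotlib 3.10.9.

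The fits were tested on simulated data with 200 changed genes in each treatment over 4290 genes. With equal spread in all treatments the shared-spread fit recovered 85.8% of genes changed by 1 on the log2 scale and 99.8% of those changed by 2, with 3.78% false among its calls. With the spreads observed here it recovered 86.9% and 99.6%, but 26.2% of its calls were false, against 4.38% with 1 weight per treatment. Simulated treatments with no change and the observed spreads gave 517 false calls for IPTG, 183 for paromomycin and 2 for kanamycin, and none in the other 14 treatments. With weights, limma made 0 calls in all 17 unchanged treatments. On simulated class comparisons the fit over drugs recovered 95% and 100% of changed genes with 9 false calls over 4290 genes. How far drugs of a class differed in that simulation is not given here, so its recovery may not hold for the real comparison. There the ribosomal protein medians ran from -0.17 to 1.37 within the translation inhibitors. The contrast of a combination with the sum of its components gave 0 false calls over 4290 simulated genes that did not differ from the sum. No result is given for that contrast with the observed spreads, so this 0 sets no limit on false calls in the real contrasts.

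Before the data were examined, 30 gene lists, the drug classes, the tests and the rule for named genes were fixed. The rule took the 5 highest and 5 lowest called genes with a symbol per treatment, the 2 to 4 members with the largest absolute value for each described list, and the lac genes. For each class comparison it took the 10 genes with the smallest p and the 10 called the same way in most translation inhibitors. For each combination it took the 5 highest and 5 lowest genes called in it and not called the same way in either component. It also took the 5 with the largest difference from the sum. List members named in the text without a passed test are given as values. Lists were tested with camera at a preset correlation of 0.01 and again with the correlation estimated from the data, with Benjamini-Hochberg adjustment over all 510 pairs of list and treatment. Each list median was also placed among 10000 random lists of the same size matched on 10 bins of signal level. Genes called are given over all genes tested and "adjusted over the list alone". Drug classes were compared by two-sided exact permutation over drugs, with 95% intervals from inverting that test, and per gene by limma with the drug as the replicate.

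Control membranes fell into 4 sets by their correlation over genes (grouped where 1 minus r was under 0.3 on average linkage). The median r was 0.916 within sets over 200 pairs and 0.468 between sets over 361 pairs. Set 1 held IPTG, set 2 erythromycin, promethazine and chloramphenicol replicate 1, and set 3 kanamycin, paromomycin, streptomycin, erythromycin with promethazine and chloramphenicol replicate 2. Set 4 held the other 9 treatments. No pair of control membranes held the same values, the highest correlation between any pair being 0.986, so no shared control was found. Comparisons between drugs were repeated within set 4 where it held drugs of both classes.

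Alternatives fixed in advance were median and quantile normalization, floors of 0.05 and 0.2, leaving out the lowest 25% of genes by level, leaving out each replicate or drug, thresholds of 3 and 1.5 on the score, median subtraction and a robust z. When a replicate was left out, the remaining sample was assumed to vary like those of the other treatments. The number of membranes limits the precision of every value.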

Results

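Gene expression in Escherichia coli was profiled after exposure to single antibacterial drugs, to drug pairs that the series title calls synergistic, and to IPTG. Of the 13 single drugs, 9 inhibit translation: chloramphenicol and erythromycin act on the large ribosomal subunit, puromycin ends peptide chains, and hygromycin B, kanamycin, paromomycin, spectinomycin, streptomycin and tetracycline act on the small subunit. The other 4 were nalidixic acid, a gyrase inhibitor, rifampicin, an RNA polymerase inhibitor, sulfisoxazole, a folate synthesis inhibitor, and promethazine, a phenothiazine. Every treatment had 2 replicates, each with its own control membrane. Duplicate spots correlated at 0.987 or above on every membrane, with a median of 0.995. Spearman rho between the log2 ratios of the replicates ran from -0.298 under IPTG to 0.685 under hygromycin B. The next lowest were 0.031 under kanamycin, 0.130 under erythromycin and 0.177 under paromomycin.

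Over all treatments limma called 2908 changes, of which 2058 were higher and 850 lower than control. With 1 weight per treatment the count was 4553, with 2734 higher and 1819 lower, and 1696 calls were shared by both fits. With quantile normalization the split was 1629 higher and 1240 lower. On the deposited relative volume difference 1857 values lay at or above 2 and 2121 at or below -2, and 1018 of the limma calls were among them. Of 510 pairs of gene list and treatment, 106 passed camera at the preset correlation, 50 upward and 56 downward. With an estimated correlation 6 pairs passed: the lac operon under IPTG, heat shock under kanamycin, the SOS response under nalidixic acid, cold shock under erythromycin, and ribosomal proteins and translation factors under promethazine.

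**Figure D1:**
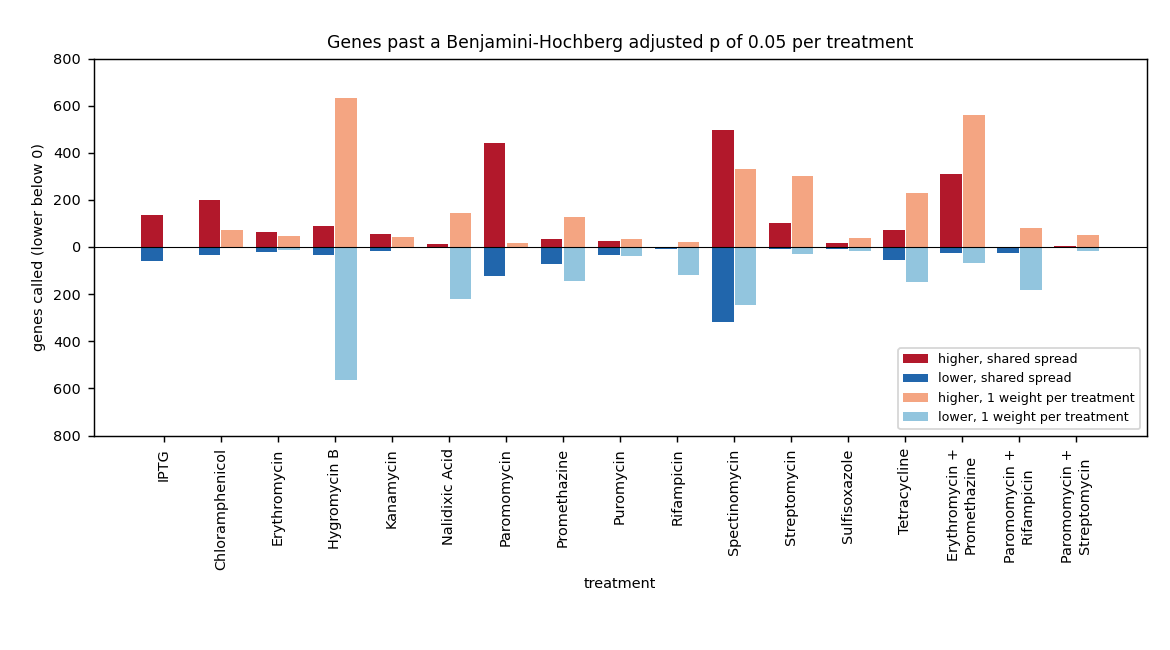
Bars give the number of genes called higher (above 0) or lower (below 0) than control in each treatment at an adjusted p of 0.05, with a spread shared by all treatments (dark) and with 1 weight per treatment (light). The 814 calls under spectinomycin were the most with a shared spread, and the 1196 under hygromycin B the most with weights.

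IPTG, which releases the lac operon from its repressor, gave a check of the labels and of the direction of the ratios. All 3 lac genes rose: lacA, the acetyltransferase, by a log2 ratio of 4.01 ± 0.26 (SE, n = 2; 16.1-fold; limma adjusted p = 2.3e-09), lacZ, beta-galactosidase, by 3.79 ± 0.38 (13.8-fold; adjusted p = 1.7e-05), and lacY, the permease, by 3.21 ± 0.35 (9.26-fold; adjusted p = 7.21e-06). In the 16 other treatments no mean lac ratio exceeded the 0.86 of lacY under paromomycin, where replicate 1 alone gave 1.74, and lacA fell under tetracycline by 1.05 on the log2 scale (adjusted p = 0.0302). As a list the lac operon passed camera (adjusted p = 3.01e-13, and 0.00475 with an estimated correlation). The other genes with large ratios were ygiZ (at least 6.07-fold higher on the mean) and mocA (at least 4.45-fold), both with control spots at the floor, and gph (log2 ratio -1.56), baeR (-1.37), zur (-1.30), murI (-1.30) and phnJ (-1.27). With 1 weight per treatment lacA (adjusted p = 0.00102) was the 1 gene left of 195, and lacZ and lacY had adjusted p of 0.105 and 0.216. The replicates of IPTG correlated at rho = -0.298, and replicates 1 and 2 gave 3.88 and 1.32 for ygiZ, 3.20 and 1.10 for mocA, -0.11 and -2.64 for baeR and -2.40 and -0.19 for zur. The fit with a shared spread called 135 higher and 60 lower, with 138 and 110 after median normalization, 141 and 117 after quantile normalization and 4 and 14 on the score. Without replicate 1 the total was 394, with gph at 0.01 and murI at 0.07, and without replicate 2 it was 725.

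**Figure D2:**
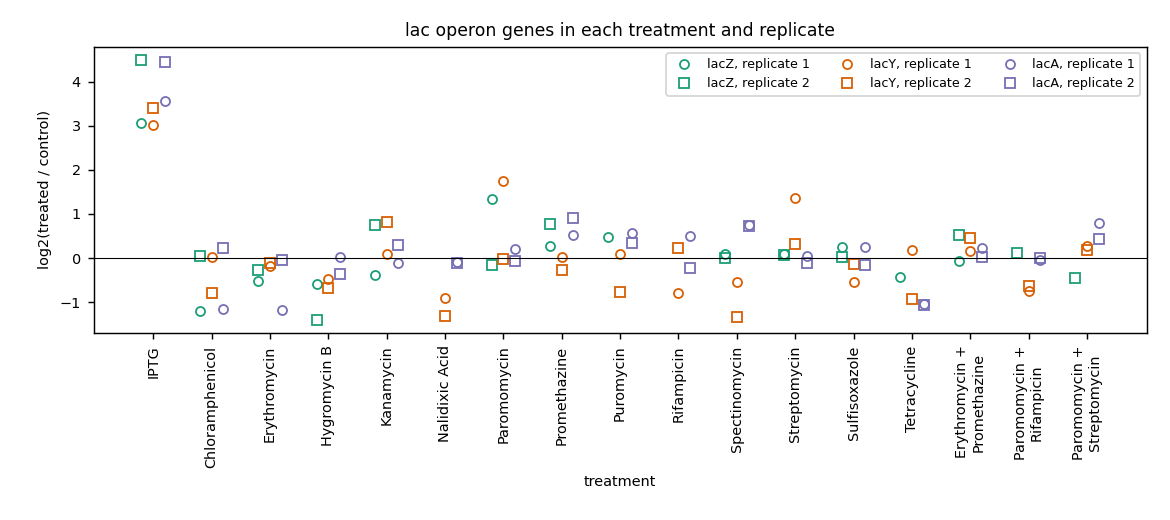
Points give the log2 ratio of treated over control for lacZ, lacY and lacA in each replicate of each treatment, circles for replicate 1 and squares for replicate 2. Under IPTG all values lay between 3.02 and 4.50, above every value of the other 16 treatments.

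Chloramphenicol raised ribosomal protein genes: 39 of 54 rose and none fell (50 when adjusted over the list alone), with a median log2 ratio of 1.04, or 2.06-fold. The list passed camera (adjusted p = 3.28e-29, but 0.264 with an estimated correlation). Its largest members were rpmH at 1.71 ± 0.27 (adjusted p = 0.00105), rpsJ at 1.52 and rplU at 1.5. Among cold shock genes 4 of 10 rose (6 adjusted over the list alone), led by cspG, a cold shock protein, at 1.98 ± 0.23 (adjusted p = 1.99e-05), infB, initiation factor IF-2, at 1.57, and nusA, a transcription elongation factor, at 1.03; the list's adjusted p was 0.000114, and 0.101 with an estimated correlation. Further high genes were rbsD of ribose uptake at 2.06, the insertion sequence gene insF2 at 2.04 and ybeU at 1.93. Flagellar and chemotaxis genes had a median of -0.23, and 7 of 51 fell (11 adjusted over the list alone), among them flgJ (-1.21), flgF (-1.12), flgE, the hook protein (-1.09), and flgB (-1.05); the list's adjusted p was 1.26e-08, and 0.454 with an estimated correlation. Genes of aerobic respiration had a median of -0.23, and nuoL (-0.87) and nuoJ (-0.61) of NADH dehydrogenase I were among the 3 of 21 that fell (4 adjusted over the list alone; list adjusted p = 2.16e-06, and 0.306 with an estimated correlation). The tryptophanase leader gene tnaC (-1.24) and srlB of sorbitol uptake (-1.08) also fell. Limma called 198 genes higher and 36 lower, with 74 and 3 under per-treatment weights, where flgB, flgE, flgF, nuoJ, nuoL, srlB and tnaC did not pass. Without replicate 1 it called 377 genes and without replicate 2 it called 13, and the chloramphenicol score did not match these intensities. Among the genes above, it was -0.35 for cspG and -0.34 for rbsD, and it was -2.03 for the cold shock gene cspB, whose log2 ratio of 0.94 did not pass. The score was also short of 2 for the ribosomal protein genes rpmH (1.75), rpsJ (1.73) and rplU (1.11). It passed its threshold, in the direction of the ratio, for infB (6.79), flgF (-2.50), flgE (-5.39), flgB (-5.66) and nuoJ (-3.00). Replicates 1 and 2 gave 0.85 and 2.18 for rpsJ, 1.36 and 2.71 for insF2, 1.26 and 2.59 for ybeU, -1.93 and -0.49 for flgJ, -1.82 and -0.43 for flgF, -1.80 and -0.37 for flgE, -1.56 and -0.53 for flgB, -1.59 and -0.16 for nuoL, and -0.77 and -1.72 for tnaC.

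Erythromycin also raised ribosomal protein genes, of which 19 of 54 rose and none fell (44 adjusted over the list alone). Their median log2 ratio was 0.85, or 1.81-fold (camera adjusted p = 3.94e-44, and 0.153 with an estimated correlation). The highest were rplQ at 1.51 ± 0.30 (adjusted p = 0.00726), rplI at 1.51, rplU at 1.5 and rpsJ at 1.47, and ymgG outside the list reached 1.42. Cold shock genes had a median of 0.45, and infB (1.40 ± 0.26, adjusted p = 0.00342), cspG (1.05) and nusA (0.77) were the 3 of 10 that rose (5 adjusted over the list alone). That list passed camera with a preset (adjusted p = 7.98e-08) and with an estimated correlation (adjusted p = 0.0143). Of 11 translation factor genes infB and efp, elongation factor P (0.92), rose (5 adjusted over the list alone; list adjusted p = 1.6e-07, and 0.0726 with an estimated correlation). The lowest called genes were nuoL (-1.44 ± 0.25, adjusted p = 0.00201), dps, which protects DNA in starved cells (-1.34), cybC (at least 2.42-fold lower, with treated spots at the floor), the porin gene phoE (-0.93) and the toxin gene hipA (-0.91). In all, 63 genes rose and 20 fell, against 48 and 13 with weights, where cybC and efp did not pass. Without replicate 1 the call count was 35, and without replicate 2 it was 264. The replicates gave -1.92 and -0.76 for dps, -1.85 and -0.70 for cybC and -1.47 and -0.36 for hipA.

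Hygromycin B had the closest replicates. Ribosomal protein genes rose in 24 of 54 cases with none lower (45 adjusted over the list alone), with a median of 0.92, or 1.89-fold (camera adjusted p = 8.53e-38, and 0.184 with an estimated correlation). The leading members were rplQ at 1.47 ± 0.30 (adjusted p = 0.00831), rplE at 1.33 and rplU at 1.32, with rplX at 1.37 not passing (adjusted p = 0.086). The ribosome assembly GTPase gene obgE reached 1.43 ± 0.16 (adjusted p = 5.39e-05) and infB 1.40. Cold shock genes had a median of 0.35, with infB and the RNA helicase gene deaD (0.60) as the 2 of 10 that rose, also adjusted over the list alone (list adjusted p = 0.0037, and 0.208 with an estimated correlation). The lowest genes were the leader peptide genes tnaC (at least 4.03-fold lower) and pyrL at -1.52 ± 0.22 (adjusted p = 0.000852), followed by ydeN (-1.36), the leader gene leuL (-1.33) and the tryptophan transporter gene tnaB (-1.18). Limma called 90 genes higher and 36 lower. With weights these were 633 and 563, and without replicate 1 or 2 the totals were 5 and 1.

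Kanamycin raised heat shock genes, with 11 of 19 higher and none lower (15 adjusted over the list alone). The median log2 ratio was 1.29, or 2.45-fold, and the list passed camera with a preset (adjusted p = 2.41e-26) and with an estimated correlation (adjusted p = 0.00475). The small heat shock protein gene ibpB reached 2.37 ± 0.28 (adjusted p = 4.87e-05), the chaperonin gene groS 2.36, the chaperone gene dnaK 1.89 and the disaggregase gene clpB 1.75. Outside the list yehC rose by 3.08 ± 0.53 (adjusted p = 0.00141; 1.35 and 4.80 in replicates 1 and 2) and yhdN by 1.80. The lowest genes were narG of nitrate reductase (at least 6.27-fold lower, with treated spots at the floor), fliA, the flagellar sigma factor, at -2.14 ± 0.27 (adjusted p = 5.18e-05), flgJ (-1.31), fliC, flagellin (-1.30), and nuoI (-1.28). Together with flgB (-1.24) these made 4 of 51 flagellar genes that fell, also adjusted over the list alone, for a median of -0.15 (list adjusted p = 5.27e-08, and 0.467 with an estimated correlation). Outer membrane genes had the same median, and lpp, the major lipoprotein (-0.96), and ompA (-0.78) were the 2 of 13 that fell (4 adjusted over the list alone; list adjusted p = 0.000335, and 0.184 with an estimated correlation). In all, 57 genes rose and 16 fell, with 50 and 25 after quantile normalization and 41 and 57 on the score. Over all genes the replicates of kanamycin correlated at Spearman rho = 0.031. They gave 1.53 and 3.19 for groS, -2.08 and -0.53 for flgJ and -1.93 and -0.62 for nuoI. Weights gave 41 and 5, where narG, nuoI, flgB, lpp and ompA did not pass, and without replicate 1 the count was 149.

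Nalidixic acid raised SOS genes, the DNA damage regulon. Of 22 members 6 rose and none fell (7 adjusted over the list alone), and the list passed camera with a preset (adjusted p = 2.82e-18) and with an estimated correlation (adjusted p = 0.00677). The recombinase gene recA rose by 2.80 ± 0.14 (6.95-fold; adjusted p = 9.26e-12), dinI by 2.43, the division inhibitor gene sulA by 1.66 and the excision repair gene uvrA by 1.63. The list median was 0.26. Outside it tdcE of threonine degradation rose by 2.49 ± 0.26 (adjusted p = 5.83e-06). Genes of the TCA cycle had a median of 0.46 and a camera adjusted p of 4.53e-08 (0.184 with an estimated correlation). None of its 16 members passed limma (7 adjusted over the list alone, 11 with weights), the largest being sucA at 0.90 (adjusted p = 0.349). The lowest genes were the leader gene ilvL (at least 2.18-fold lower), glgC of glycogen synthesis (-1.02), cspA, the major cold shock protein (-1.0 ± 0.15, adjusted p = 0.000902), the ferrous iron transporter gene feoB (-1.0) and rclB (-0.92). Limma called 12 genes higher and 5 lower, and 145 and 221 with weights, and the score gave 137 and 151. The totals without replicate 1 and 2 were 6 and 3, and with the lowest 25% of genes by level left out the total was 8.

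Paromomycin gave both patterns. Heat shock genes had a median of 0.91, or 1.88-fold, with 11 of 19 higher (13 adjusted over the list alone; camera adjusted p = 4.63e-08, and 0.172 with an estimated correlation). The leading members were groS at 2.45 ± 0.54 (adjusted p = 0.00439), ibpB at 2.09, the protease subunit gene hslU at 2.07 and the chaperonin gene groL at 1.91, of which replicate 1 carried most: replicates 1 and 2 gave 4.26 and 0.63 for groS, 3.40 and 0.74 for hslU and 3.24 and 0.58 for groL. Ribosomal protein genes had a median of 0.48, with 21 of 54 higher and none lower (23 adjusted over the list alone; camera adjusted p = 1.45e-07, and 0.758 with an estimated correlation), led by rpsG at 2.21 ± 0.26 (adjusted p = 1.14e-05), rplX at 2.01, rpsB at 1.53 and rpmD at 1.40. The oligopeptidase gene prlC reached 2.16. Outer membrane genes had a median of -0.21, with 4 of 13 lower and 1 higher (4 and 2 adjusted over the list alone; list adjusted p = 0.0278, and 0.454 with an estimated correlation): the protease gene ompT at -1.59 ± 0.17 (adjusted p = 9.81e-06), the porin gene ompF at -0.94, lpp at -0.60 and the nucleoside channel gene tsx at -0.59. Other low genes were gloA, glyoxalase I (-0.90), feoA (-0.87; -1.34 and -0.41 in the replicates) and yqaB (-0.87; -1.24 and -0.50). The 442 higher and 124 lower calls came to 295 and 207 after quantile normalization, to 69 in total without replicate 1 and to 1130 without replicate 2. With 1 weight per treatment 16 genes were higher and 1 lower, prlC (adjusted p = 0.00539), rpsG (0.0425) and ompT (0.0435) among them, while groS, ibpB, hslU, groL, rplX, rpsB, rpmD, ompF, lpp, tsx, gloA, feoA and yqaB did not pass.

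Puromycin raised heat shock genes, with 5 of 19 higher and none lower (9 adjusted over the list alone). Their median was 0.35 (camera adjusted p = 1.79e-07, and 0.184 with an estimated correlation). The chaperone gene dnaK rose by 1.72 ± 0.30 (adjusted p = 0.00655), the membrane protease gene ftsH by 1.44 and ibpB by 1.41, while groS stood at 1.44 with an adjusted p of 0.234. The highest gene was crl, a regulator of the stationary phase sigma factor, at 1.82 ± 0.24 (adjusted p = 0.000893), and the iron repressor gene fur rose by 1.29. Of the RNA polymerase and elongation factor genes rpoB, the beta subunit, fell by 1.40 on the log2 scale (adjusted p = 0.00394). It was the 1 of 10 to fall, also adjusted over the list alone, with nusG at -0.35, rpoA at -0.30 and nusB at -0.30 not passing (list median -0.21, adjusted p = 0.0243, and 0.599 with an estimated correlation). Without replicate 1 nusB stood at 0.61. The other low genes were ygiZ (-1.63), mltF (-1.43), cyoD of cytochrome oxidase (-1.38) and the alcohol dehydrogenase gene adhE (-1.38). Limma called 27 genes higher and 32 lower, with 35 and 40 under weights and 9 in total without replicate 1. The replicates gave 2.00 and 0.89 for ftsH and 1.76 and 0.83 for fur.

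Spectinomycin gave the largest changes in ribosomal protein genes, with 49 of 54 higher and none lower (52 adjusted over the list alone). The median log2 ratio was 1.37, or 2.59-fold (camera adjusted p = 8.34e-30, and 0.263 with an estimated correlation). The members rplX at 2.71 ± 0.42 (6.54-fold; adjusted p = 8.78e-05), rpsT at 2.22, rplQ at 2.14 and rplV at 2.03 led the list. Translation factors rose in 8 of 11 cases, also adjusted over the list alone, with a median of 1.00, led by infB at 2.42 ± 0.26 (adjusted p = 1.96e-06), efp at 1.56, infA at 1.55 and the elongation factor Tu gene tufA at 1.36; the list's adjusted p was 8.81e-05, and 0.192 with an estimated correlation. RNA polymerase and elongation factor genes rose in 7 of 10 cases (8 adjusted over the list alone), with a median of 0.77 and nusB at 1.52, nusA at 1.13, rpoB at 1.05 and rpoA at 0.99 (list adjusted p = 0.000104, and 0.34 with an estimated correlation). The GTPase gene obgE reached 2.24 and ygdQ 2.31. The lowest genes were yagL at -2.25 ± 0.18 (adjusted p = 7.02e-08), csgE (-1.72) and csgD (-1.69) of curli fibre formation, phoU of phosphate regulation (-1.65) and the sodium antiporter gene nhaA (-1.64). For tufA the replicates gave 0.64 and 2.08. Limma called 495 genes higher and 319 lower, and 420 and 428 after quantile normalization. Weights gave 330 and 248, and without replicate 1 and 2 the totals were 513 and 277.

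Streptomycin raised heat shock genes, with ibpB (1.17 ± 0.28, adjusted p = 0.029) among the 2 of 19 that rose (4 adjusted over the list alone), and with groS at 1.19, clpB at 0.80 and groL at 0.77 passing with weights alone (adjusted p = 0.0437, 0.0234 and 0.0294). The list median was 0.41 (camera adjusted p = 0.00865, and 0.523 with an estimated correlation). The highest genes were hisF of histidine synthesis at 1.96 ± 0.33 (adjusted p = 0.00371), rdgC at 1.66, yeeR at 1.54, yghR at 1.44 and ydhV at 1.41. Outer membrane genes had a median of -0.36, with lpp (-0.83 ± 0.20, adjusted p = 0.0263) and tsx (-0.62) as the 2 of 13 that fell (5 adjusted over the list alone), and with ompA at -0.70 and ompF at -0.66 not passing (list adjusted p = 2.26e-05, and 0.115 with an estimated correlation). Glycolysis genes had a median of -0.19 with none of 17 past limma, adjusted over the list alone or with weights, and the largest was ptsI at -0.42 (adjusted p = 0.364; list adjusted p = 0.000335, and 0.342 with an estimated correlation). Polyphosphate kinase, ppk (-1.12), rutC of pyrimidine degradation (-0.71) and xynR (-0.65) fell as well. The 100 higher and 7 lower calls came to 56 and 12 after median normalization and 42 and 13 after quantile normalization, while on the score 152 of 288 were lower. The replicates gave -1.58 and -0.67 for ppk, -0.91 and -0.38 for xynR and -0.39 and -0.85 for tsx. Weights gave 303 and 30, and without replicate 1 the total was 10.

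Tetracycline raised ribosomal protein genes, with 8 of 54 higher and none lower (22 adjusted over the list alone). Their median was 0.58, or 1.49-fold (camera adjusted p = 4.28e-15, and 0.467 with an estimated correlation). The members rpmH at 1.87 ± 0.27 (adjusted p = 0.000267) and rplV at 1.14 rose, while rplX at 1.45 and rpmG at 1.12 did not pass. The highest genes were the toxin genes hokD (at least 5.03-fold) and mqsR (1.82), tpr (at least 4.40-fold) and ligB (1.87, with 0.47 and 3.28 in replicates 1 and 2). Flagellar genes had a median of -0.26, and 7 of 51 fell and none rose (11 and 1 adjusted over the list alone), among them flgB at -2.01 ± 0.30 (adjusted p = 0.000304), flgE at -1.54, flgC at -1.08 and flgA at -1.0 (list adjusted p = 1.06e-08, and 0.454 with an estimated correlation). Genes of aerobic respiration had a median of -0.32, and 5 of 21 fell (9 adjusted over the list alone), among them cyoC (-1.27) and cyoD (-1.23) of cytochrome oxidase, nuoL (-1.06) and nuoK (-0.63); the list's adjusted p was 6.31e-08, and 0.208 with an estimated correlation. The threonine regulator gene tdcA (-2.37 ± 0.26, adjusted p = 1.13e-05), the maltose activator gene malT (at least 4.55-fold lower), adhE (-1.94) and tnaC (at least 3.61-fold lower) also fell. In all, 72 genes rose and 54 fell, with 228 and 147 under weights, and on the score 105 and 181. The totals without replicate 1 and 2 were 44 and 26.

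Promethazine moved ribosomal protein genes the other way. Of 54 genes 39 fell and none rose (51 adjusted over the list alone), with a median log2 ratio of -1.12, or 0.461 of the control level, and the list passed camera with a preset (adjusted p = 1.03e-80) and with an estimated correlation (adjusted p = 0.0274). The lowest were rpsS at -1.90 ± 0.33 (adjusted p = 0.00153), rplP at -1.76, rplT at -1.73 and rplI at -1.73. Translation factors had a median of -0.77, and 4 of 11 fell (8 adjusted over the list alone), including tsf (-0.98), prfB (-0.97) and infA (-0.93), with infB at -0.95 not passing; that list also passed with an estimated correlation (adjusted p = 4.34e-12 and 0.0143). ATP synthase genes had a median of -0.43, with atpA (-0.68) as the 1 of 9 that fell (2 adjusted over the list alone; list adjusted p = 0.000423, and 0.432 with an estimated correlation). Heat shock genes had a median of 0.27, and clpB (1.76 ± 0.24, adjusted p = 0.000143), the chaperone gene htpG (1.49), dnaK (1.12) and htpX (0.80) were the 4 of 19 that rose (5 adjusted over the list alone; list adjusted p = 1.94e-08, and 0.153 with an estimated correlation). In the mar-sox-rob regulon 3 of 21 rose (4 adjusted over the list alone), including fpr (1.23) and the superoxide dismutase gene sodA (1.10), with fumC at 1.27 and marA at 1.02 not passing (list adjusted p = 1.51e-05, and 0.263 with an estimated correlation). The highest genes were asnA, asparagine synthetase, at 2.29 ± 0.21 (adjusted p = 7.07e-07), the periplasmic chaperone gene spy at 1.94, the copper exporter gene copA at 1.80 and yhcN at 1.72, and flgB fell by 1.87. The replicates gave -0.96 and -2.51 for rplT, 1.51 and 0.69 for sodA and 2.67 and 0.94 for copA. Limma called 36 genes higher and 72 lower, with 128 and 143 under weights. The totals without replicate 1 and 2 were 33 and 26.

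Rifampicin gave 8 calls, all lower. They included fdoG of formate dehydrogenase (at least 2.88-fold lower), flgB at -1.52 ± 0.30 (adjusted p = 0.0302), aspA, aspartase (-1.51), maeB, a malic enzyme (-1.30), and cspA (-1.09 ± 0.15, adjusted p = 0.00144). Ribosomal protein genes had a median of -0.57 and a camera adjusted p of 1.07e-25 (0.325 with an estimated correlation). None of the 54 passed limma (21 lower adjusted over the list alone, 24 lower with weights), and the largest were rplX at -1.94 (adjusted p = 0.0616), rpsS at -0.98, rplJ at -0.94 and rpmD at -0.91. Cold shock genes had a median of -0.20, with cspA as the 1 of 10 to fall (3 adjusted over the list alone) and cspB at -1.24 and infB at -0.96 not passing (list adjusted p = 1.77e-05, and 0.0604 with an estimated correlation). TCA cycle genes had a median of -0.35, with none of 16 called over all genes and 1 adjusted over the list alone, the largest being gltA, citrate synthase, at -0.73 (list adjusted p = 0.000481, and 0.454 with an estimated correlation). At an unadjusted p under 0.05 there were 247 genes, and 20 higher and 118 lower calls with weights. Without replicate 1 there were 2 calls and without replicate 2 none.

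Sulfisoxazole gave 16 higher and 9 lower calls. The highest genes were feoC of ferrous iron uptake at 1.38 ± 0.26 (adjusted p = 0.0127), citD at 1.20, yfeK at 1.16, yegP at 1.15 and yieE at 1.11. The leader genes leuL (-1.62 ± 0.23, adjusted p = 0.00166) and pyrL (-1.32) were the lowest, followed by yagL (-1.17), crp, the catabolite regulator (-1.15), and nhaA (-1.0). Glycolysis genes had a median of 0.30, with none of 17 called over all genes and 3 adjusted over the list alone, and with gapA at 1.10 (adjusted p = 0.15), ptsH at 1.03, crr at 0.86 and ptsI at 0.48 as the largest (list adjusted p = 0.00132, and 0.41 with an estimated correlation). Folate genes, which the drug's target belongs to, did not pass camera in any treatment. The split was 15 and 13 after quantile normalization and 38 and 16 with weights, and without replicate 1 the total was 82. The score put 63 higher and 99 lower, a balance that turned at a score threshold of 3, with 33 higher and 27 lower. The replicates gave 1.87 and 0.53 for citD and 0.65 and 1.64 for yegP.

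**Figure D3:**
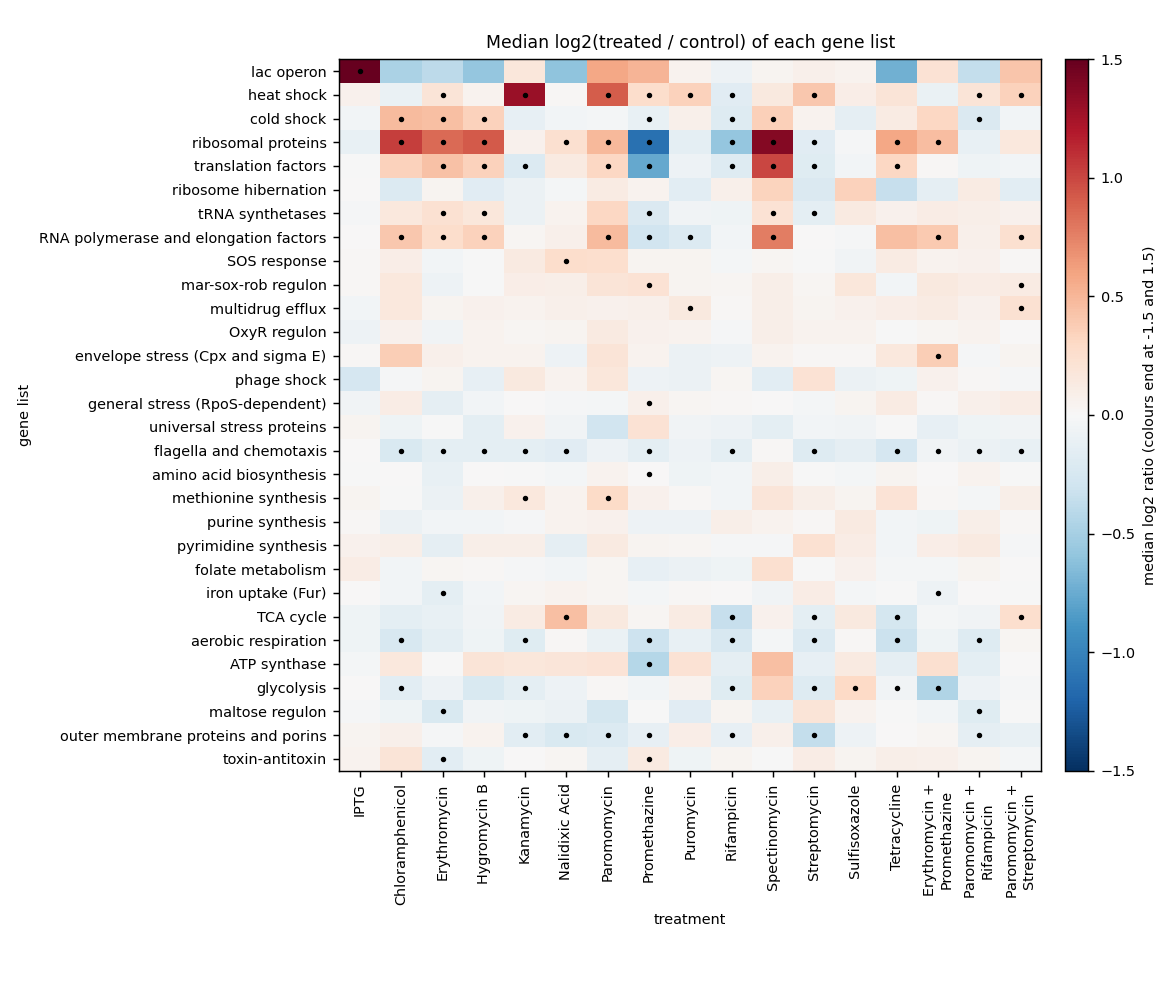
Colours give the median log2 ratio of treated over control for each of the 30 gene lists (vertical axis) in each treatment (horizontal axis), and dots mark lists past camera at the preset correlation, adjusted p under 0.05. Ribosomal proteins ran from -1.12 under promethazine to 1.37 under spectinomycin, and heat shock from -0.17 under rifampicin to 1.29 under kanamycin.

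Across the 9 translation inhibitors 4 genes were called higher in 6 drugs and 12 in 5, and no gene list was tested for enrichment among them. The ribosomal protein genes rplV (mean log2 ratio 0.95 ± 0.65, SD over drugs), rpsT (0.87) and rplW (0.64) and the gene yhdN (0.87) rose in 6 drugs each. The genes obgE (1.00), infB (0.94), rplU (0.80), miaA, which modifies tRNA (0.74), hns, a nucleoid protein (0.74), and yfjW (0.70) rose in 5, as did rplD, rplB, rplC, rpmB, the primosome gene priB and the transcription factor gene nusA. With 1 weight per treatment rplV rose in 4 drugs, rpsT and rplW in 5, yhdN, yfjW, rplD and priB in 3 and miaA in 6, and the others again in 5. In the 4 other drugs rplV, rpsT and rplW averaged -0.55, -0.31 and -0.57, and yhdN 0.31. No gene fell in more than 3 translation inhibitors. After median or quantile normalization the ribosomal protein medians kept their direction and at least 94.1% of their size under chloramphenicol, erythromycin, hygromycin B, paromomycin, spectinomycin, tetracycline, promethazine and rifampicin. Because calls were counted per drug, these numbers do not test a difference between the classes.

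Tested as classes, no list separated the 9 translation inhibitors from the 4 other drugs after adjustment over 30 lists. The nearest were cold shock genes, whose median was higher by 0.31 (95% interval 0.06 to 0.57) on the log2 scale and above 0 in 7 of 9 translation inhibitors against 0 of 4 others (exact permutation p = 0.0168, adjusted p = 0.315). Ribosomal protein genes were higher by 0.92 (0.16 to 1.68; above 0 in 7 of 9 against 1 of 4; exact permutation p = 0.021, adjusted p = 0.315). RNA polymerase genes were higher by 0.35 (0.00 to 0.71; exact permutation p = 0.0462, adjusted p = 0.399) and translation factors by 0.47 (-0.01 to 0.98; p = 0.0531 and adjusted p = 0.399 by the same test). Within control membrane set 4 the differences were 0.35 for cold shock (exact permutation p = 0.0571) and 0.80 for ribosomal proteins (p = 0.143, 35 splits). The smallest p there was that of outer membrane genes (difference 0.20, exact permutation p = 0.0286, the smallest that 35 splits can give and not adjusted over lists), which over all drugs differed by 0.09 (p = 0.316 by the same test). Of 4058 genes limma with the drug as replicate called 0, with 386 at an unadjusted p under 0.05 and a smallest adjusted p of 0.252. The genes with the smallest p were topA, topoisomerase I, higher by 0.87 ± 0.17 (SE), bioF (-0.37), purC (-0.45), bssS (0.77), rplO (0.81), metJ, the methionine repressor (0.70), pdeL (0.71), deoD (-0.60), rpsN (1.36) and yfjW (0.94), none of which passed. The ratios of topA, bssS, metJ and pdeL were above 0 in 9 of 9 translation inhibitors and in 1, 2, 1 and 0 of 4 others, but these genes were picked by the same comparison.

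The aminoglycosides hygromycin B, kanamycin, paromomycin and streptomycin, with the aminocyclitol spectinomycin, were set against chloramphenicol, erythromycin, puromycin and tetracycline. Kanamycin, paromomycin and hygromycin B carry a deoxystreptamine ring, streptomycin a streptidine ring, and spectinomycin no amino sugar; doses and times are not given, so the readouts may not be matched. No list differed after adjustment. Purine synthesis came nearest, with a median higher by 0.08 (95% interval 0.00 to 0.14; exact permutation p = 0.0397, adjusted p = 0.452). Heat shock genes differed by 0.40 (-0.27 to 1.12; exact permutation p = 0.238) and ribosomal protein genes by -0.05 (-1.03 to 0.93; p = 0.865 by the same test), intervals that leave room for large differences either way. Within control membrane set 4, with hygromycin B and spectinomycin against puromycin and tetracycline, both signs turned, to -0.17 for heat shock and 0.93 for ribosomal proteins (exact permutation p = 0.333 for both, 6 splits). Of 4080 genes limma called 0, with 172 at an unadjusted p under 0.05 and a smallest adjusted p of 0.98. The smallest p belonged to flgE (difference 0.67), with yafU, gabT, metB (0.87), the chaperone gene htpG (0.73), rcnB (-0.46), ynjD, ybiB (0.92), rlmD and hslU (0.95) next. Within the class, correlations across genes ran from -0.080 for spectinomycin with streptomycin to 0.518 for hygromycin B with spectinomycin. The highest were those of pairs within 1 control membrane set: hygromycin B with spectinomycin in set 4, and kanamycin with paromomycin (0.441) and with streptomycin (0.429) in set 3, while paromomycin with streptomycin in that set stood at 0.179.

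Ribosome inhibitors have been grouped by whether they induce heat shock or cold shock proteins. Kanamycin, puromycin and streptomycin had a mean heat shock median of 0.68, against 0.10 for chloramphenicol, erythromycin and tetracycline. Their cold shock medians were 0.00 and 0.35. With 3 drugs against 3, each difference was as far as the design can go (exact permutation p = 0.1 for both, the smallest p of 20 splits). The drugs also differed in control membranes, with kanamycin and streptomycin in set 3, erythromycin in set 2 and chloramphenicol in both. Set 4 held 1 drug of each group, puromycin with a heat shock median of 0.35 and a cold shock median of 0.07, and tetracycline with 0.20 and 0.12.

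**Figure D4:**
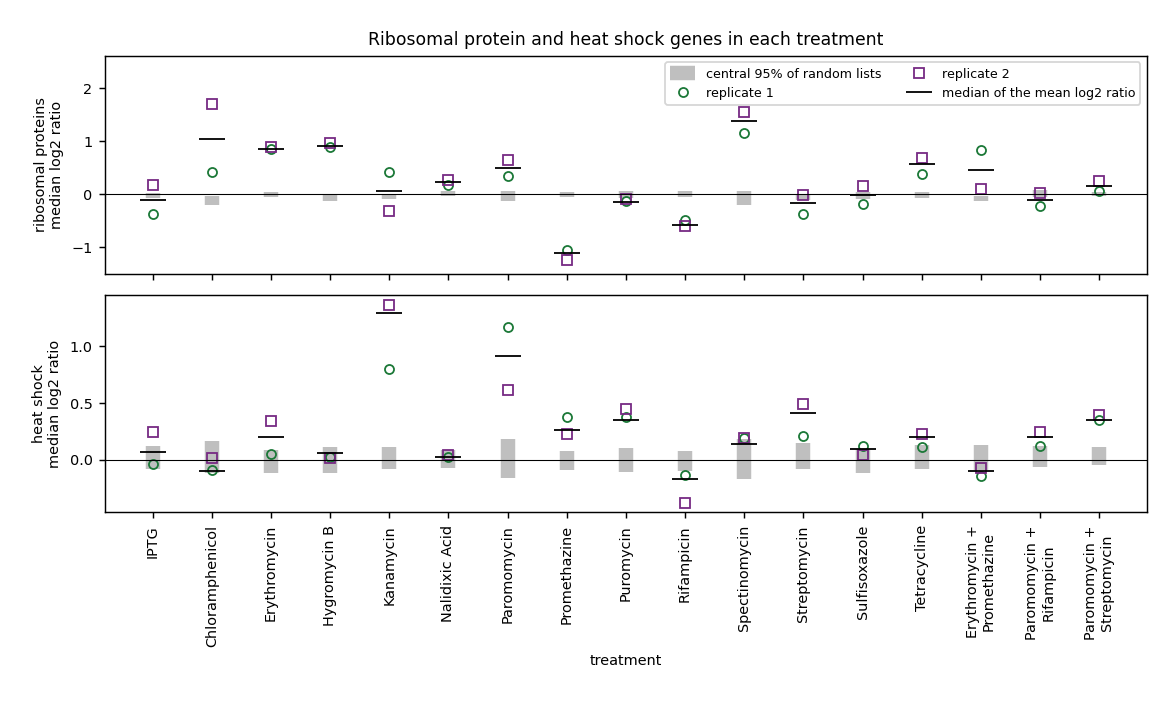
The median log2 ratio of up to 54 ribosomal protein genes (upper panel) and up to 19 heat shock genes (lower panel) is shown per treatment, as the median of the mean ratio (bar) and in each replicate (circle and square), with the central 95% of 10000 random lists matched on level in grey. Ribosomal protein genes were highest under spectinomycin (1.37) and lowest under promethazine (-1.12), and heat shock genes highest under kanamycin (1.29).

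Each drug pair was measured with control membranes of another set than at least 1 of its components, so differences between a pair and its components also carry any effect of the set. Erythromycin with promethazine was in set 3 and both components in set 2, and the pairs with paromomycin were in set 4, with paromomycin and streptomycin in set 3. Over 4193 genes erythromycin with promethazine was compared with its components. The multidrug and oxidative stress activator gene marA rose by 2.27 ± 0.28 (4.82-fold; adjusted p = 1.22e-05) in the pair, with 0.78 and 1.02 in erythromycin and promethazine alone, neither of which passed, although promethazine did with weights (adjusted p = 0.000388). Its difference from the sum of both was 0.47 ± 0.48 (adjusted p = 0.898). The highest gene was bhsA, an outer membrane stress protein, at 2.86 ± 0.20 (adjusted p = 1.04e-08), which was also called under erythromycin (0.88, adjusted p = 0.0217). Besides marA, the largest genes called in the pair and in neither component were frmR, the formaldehyde repressor (2.00), rzpD (1.93), ydeS (1.88) and the diguanylate cyclase gene dgcZ (1.82). The lowest were narG (-2.05), pflB, pyruvate formate lyase (-1.97 ± 0.21, adjusted p = 1.94e-06), gapA (-1.60), adhE (-1.47) and the glutaredoxin gene grxB (-1.16). Glycolysis genes had a median of -0.45, and 5 of 17 fell, including gapA, pykA (-0.94) and ptsI (-0.75), with ptsG at -0.74 not passing (7 adjusted over the list alone; camera adjusted p = 3.04e-10, and 0.0604 with an estimated correlation). Among envelope stress genes 3 of 16 rose, also adjusted over the list alone: spy (at least 4.14-fold), the protease genes rseP (1.59) and degP (1.13 ± 0.14, adjusted p = 1.22e-05), for a median of 0.37 (list adjusted p = 0.00674, and 0.3 with an estimated correlation). Ribosomal protein genes had a median of 0.46, against 0.85 under erythromycin and -1.12 under promethazine, with rplU (1.41) and rpmA (1.14) among the 3 of 54 that rose, also adjusted over the list alone (list adjusted p = 1.13e-05, and 0.767 with an estimated correlation).

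In that pair 306 genes were higher, sharing 24 calls with erythromycin (4.60 expected for independent lists) and 10 with promethazine (2.63 expected), and 273 were called higher in neither. The 26 lower genes shared 0 with either by limma, where 0.12 and 0.45 were expected. With weights 65 of 70 lower genes were called lower in neither. Limma called 71 genes different from erythromycin, 186 from promethazine and 15 from the sum of both, with 137, 505 and 52 under weights. Among the largest differences from the sum, asnA (-2.38 ± 0.36, adjusted p = 0.00314) and fis, a nucleoid protein (2.06 ± 0.34, adjusted p = 0.00573), passed, as did ydeS (1.73) and dgcZ (1.68), while yehC (-2.52), dnaK (-2.30) and flgB (2.26) did not. With weights dnaK (limma adjusted p = 0.0377) and flgB (limma adjusted p = 0.00866) passed too, and yehC did not. Across genes, which are not independent replicates, the pair correlated at r = 0.615 with chloramphenicol, the highest of 14 single treatments (0.331 and rank 4 on the deposited score), and at 0.214 with erythromycin (rank 7), 0.013 with promethazine (rank 13) and 0.206 with their sum. Limma called 310 genes higher and 26 lower over all genes tested in the pair. On the score the balance turned, with 164 higher and 220 lower. The split was 153 and 65 after quantile normalization, and the total was 202 without the lowest 25% by level, 134 without replicate 1 and 85 without replicate 2.

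Paromomycin with rifampicin gave 1 higher and 26 lower calls. The rpoB gene, whose product rifampicin binds, rose by 1.12 ± 0.22 (adjusted p = 0.0149), with 0.58 in each component. The lowest genes were malM of the maltose regulon at -1.93 ± 0.30 (adjusted p = 0.00179), the cold shock genes cspB (-1.87) and cspE (-1.67), yobF (-1.64), mcbR (-1.54) and the porin gene ompC (-1.5). Of 10 cold shock list members cspB and cspA (-1.10) fell, also adjusted over the list alone, with a median of -0.21 (camera adjusted p = 0.000239, and 0.115 with an estimated correlation). In the maltose list malM was the 1 of 11 to fall, also adjusted over the list alone (median -0.18, list adjusted p = 0.00214, and 0.319 with an estimated correlation). Of 25 lower genes tested in all 3 treatments, 2 were shared with paromomycin (0.738 expected) and 1 with rifampicin (0.0476 expected), and 22 were called lower in neither. Among the latter, cspE was called higher under paromomycin (log2 ratio 1.20, limma adjusted p = 0.039). With weights 181 were lower, of which 0 were shared with paromomycin (0.0431 expected), 32 with rifampicin (5.09 expected) and 149 with neither. Limma called 149 genes different from paromomycin, 1 from rifampicin and 24 from the sum, against 11, 60 and 1 with weights. The largest differences from the sum were those of ydjF (-2.66 ± 0.55, adjusted p = 0.0318), rpsG (-2.38), purK (-2.18), stfR (-2.15) and sdaA (-2.14), of which stfR and sdaA did not pass, and none of the 5 passed with weights. The pair correlated most with rifampicin (r = 0.285, rank 1 of 14), with paromomycin at 0.081 (rank 11) and with the sum at 0.204. Rifampicin and the treatments ranked next, hygromycin B (0.229), nalidixic acid (0.205) and tetracycline (0.172), had controls in set 4, as the pair did. Paromomycin was in set 3, so these ranks cannot be told apart from the set. On the deposited score rifampicin again came first (0.261). Between replicates of different number hygromycin B (0.229) stood level with rifampicin (0.224). Weights gave 82 higher and 184 lower calls, and without replicate 1 there were 0, with 16 without replicate 2.

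Paromomycin with streptomycin gave 4 calls, all higher: ibpB at 1.52 ± 0.28 (adjusted p = 0.0263), eco, a protease inhibitor (0.93), ybeT (0.77) and rutR (0.73), of which eco, ybeT and rutR were called in neither component. Heat shock genes had a median of 0.35 (camera adjusted p = 2.25e-09, and 0.115 with an estimated correlation), against 0.91 under paromomycin and 0.41 under streptomycin, with ibpB as the 1 of 19 to rise (3 adjusted over the list alone) and clpB at 1.15, groS at 1.06 and htpX at 0.72 not passing. TCA cycle genes had a median of 0.25, with none of 16 called over all genes and 2 adjusted over the list alone, and with sdhD at 0.77 the largest (list adjusted p = 0.000958, and 0.454 with an estimated correlation). Limma called 40 genes different from paromomycin, 6 from streptomycin and 106 from the sum, of which 94 were lower, against 1, 79 and 14 with weights. Among the largest differences from the sum were hisF (-2.95 ± 0.58, adjusted p = 0.0111), adk (-2.54), ybdF (-2.50) and the purine salvage gene apt (-2.49 ± 0.29, adjusted p = 0.000103), with groS (-2.58) not passing and adk not passing with weights. In the pair itself hisF stood at -0.06 and ybdF at -0.03, and at 0.28 and 0.01 without its replicate 1. The pair correlated most with paromomycin (r = 0.260, rank 1), with streptomycin at 0.105 (rank 8) and with the sum at 0.254. On the deposited score hygromycin B (0.257) came before paromomycin (0.243). Between replicates of different number it also did (0.180 against 0.130). For rutR its replicates gave 0.41 and 1.04. The score put 45 genes higher and 47 lower. Weights gave 50 higher and 17 lower calls, median normalization 5 and 1, quantile normalization 9 and 3, and the totals without replicate 1 and 2 were 18 and 2.

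**Figure D5:**
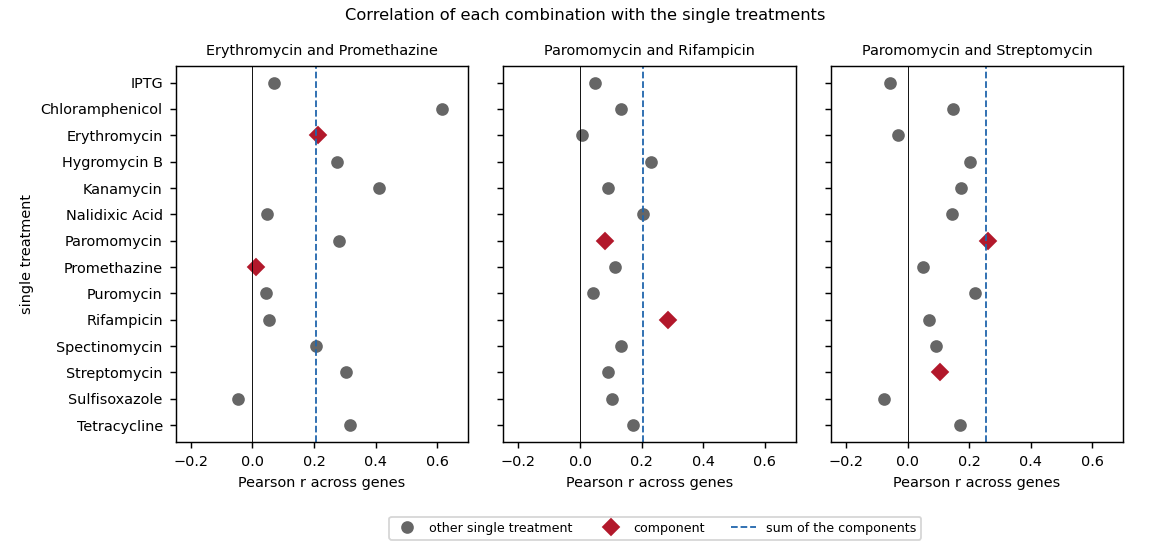
Points give the Pearson correlation across genes between each drug pair (panel) and each single treatment (vertical axis), with components as red diamonds and the correlation with the sum of the components as a dashed line. Erythromycin with promethazine had its highest correlation, 0.615, with chloramphenicol, which on the deposited score was 0.331 and rank 4 of 14, and each of the other 2 pairs with 1 of its components. Paromomycin with rifampicin shared control membrane set 4 with rifampicin and not with paromomycin. On the score, paromomycin with streptomycin had its highest, 0.257, with hygromycin B, against 0.243 with paromomycin.

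Pairs of translation inhibitors resembled each other more than pairs across classes, with a mean correlation across genes of 0.20 against 0.044 (difference 0.156, exact permutation p = 0.0112 over splits of the drugs). Within control membrane set 4 the difference was 0.165 (exact permutation p = 0.114, 35 splits). The mean correlation was 0.185 over 43 pairs of treatments in the same set and 0.062 over 77 pairs in different sets, and 0.209 over 16 pairs with chloramphenicol, whose replicates lie in different sets. The closest pairs after chloramphenicol with erythromycin plus promethazine were hygromycin B with spectinomycin (0.518), spectinomycin with sulfisoxazole (0.464) and kanamycin with paromomycin (0.441). Erythromycin and promethazine, later combined, were the least alike at -0.396. Between replicates of different number they stood at -0.205, and hygromycin B with promethazine at -0.237.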

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

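The tests of explanations below, and the fit with 1 weight per treatment, were all chosen only after the results were seen. In 60 groups of drugs and gene lists examined for a single drug far from the others, 4 stood apart, and chance alone picks out about 1 in 20 such groups. Among translation inhibitors, spectinomycin stood apart in folate metabolism genes, with a median log2 ratio of 0.24 against -0.09 to 0.03 in the others, and in glycolysis genes, with 0.35 against -0.22 to 0.06. Among the 4 other drugs, promethazine stood apart in universal stress proteins, with 0.22 against -0.07 to -0.05, and in toxin-antitoxin genes, with 0.13 against 0.03 to 0.04. For each drug pair some genes were called different from the sum of the components in a test of the difference itself. Each pair had control membranes of another set than at least 1 component, and the set cannot be told apart from the pairing in these counts. The sums for both pairs with paromomycin also carry its wide replicate spread. On a simulated unchanged paromomycin treatment the shared-spread fit made 183 false calls. Limma called 15 genes for erythromycin with promethazine, 24 for paromomycin with rifampicin and 106 for paromomycin with streptomycin, and with weights 52, 1 and 14.

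Ribosomal protein genes were higher under 6 translation inhibitors and lower under promethazine and rifampicin. Camera at the preset correlation also passed upward under nalidixic acid (median 0.24, adjusted p = 2.05e-06), not a translation inhibitor, and downward under streptomycin (-0.17, adjusted p = 2.84e-06), which is one. With an estimated correlation camera passed under promethazine alone (adjusted p = 0.0274) and gave an adjusted p of 0.153 to 0.758 under the other 7 of the 8 and 0.767 under these. Signal level was argued against, since the list median lay outside the central 95% of random lists matched on level in 8 of 8 treatments. Scaling to total intensity was argued against, since median or quantile normalization kept at least 94.1% of each median. The control membrane set was argued against as the whole cause, since erythromycin and promethazine shared set 2 and their medians lay 1.97 apart on the log2 scale, against a summed difference between replicates of 0.214. A candidate explanation that remains is the drugs' action on translation or growth, which was not tested, since growth rates are not given in the sources used here.

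The fit with a shared spread called 195 genes under IPTG and 566 under paromomycin. An unequal spread between treatments is a candidate source of these calls: on simulated unchanged treatments with the observed spreads that fit made 517 false calls for IPTG and 183 for paromomycin. The 517 exceed the 195 calls in the data, so for IPTG the simulation overshot and does not give the share of false calls. With 1 weight per treatment 1 of 195 was kept under IPTG, which was lacA, and 17 of 566 under paromomycin. The weights left the ratios as they were and widened the SE, for lacZ under IPTG (13.8-fold) from 0.38 to 0.72 and for lacY (9.26-fold) from 0.35 to 0.74. Both then missed the threshold (adjusted p = 0.105 and 0.216), so a lost call does not show that a gene was unchanged. Weak spots were not excluded as a source. Of the genes called under IPTG 25.1% lay in the lowest 25% by level, where 21.4% of all tested genes lay. Calls under IPTG were fewer with a floor of 0.2 and more with a floor of 0.05, and ygiZ and mocA had control spots at the floor. Effects of IPTG on genes outside the lac operon were not otherwise tested and remain open.

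Erythromycin with promethazine resembled chloramphenicol (r = 0.615 across genes) more than its own components. The control membrane set was argued against as the whole cause, since chloramphenicol replicate 1, measured in another set than the combination, still correlated with it at 0.395. That was above its 0.174 with kanamycin, 0.187 with paromomycin and 0.108 with streptomycin, which share the combination's set. Its correlation with tetracycline, in set 4, was as high (0.392), so this closeness was not particular to the combination. Chloramphenicol replicate 2, in the combination's set, gave 0.596 with the combination, so a part played by the set remains open. It remains open whether the chloramphenicol volumes belong to another treatment, as their mismatch with the score could mean. On the score the correlation was 0.331, rank 4 of 14, behind kanamycin (0.356), hygromycin B (0.338) and tetracycline (0.338), and erythromycin stood at 0.279. A shared mode of action of chloramphenicol and erythromycin was not tested and also remains open.

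For the class comparisons, chance cannot be excluded as a source of the gene counts. Limma called 0 genes for translation inhibitors against the other drugs, a count that each of the 100 drawn splits of the drugs reaches by construction (100 of 100, highest other 16). At an unadjusted p under 0.05 the real split gave 386 genes, and 11 of 100 splits gave as many, with a highest other of 638. For aminoglycosides and spectinomycin against other translation inhibitors limma also called 0, again reached by 100 of 100 splits by construction (highest other, 32). At an unadjusted p under 0.05 there were 172 genes, and 43 of 100 splits gave as many, with a highest other of 585.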

How the results depend on the processing

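The weights per treatment, the score in place of ratios for comparing drugs, and the restriction to control membrane set 4 were chosen after seeing the data; the other alternatives were planned. The class comparisons of gene lists and of genes and lacA under IPTG stayed on their side of the threshold in the alternatives run for them. Camera at the preset correlation gave 97 to 108 list calls, against 6 with an estimated correlation. The heat and cold shock comparison cannot give an exact permutation p under 0.1, so no setting can bring it past the threshold. Whether its differences keep their size in other settings is not given here. Of single genes named, median normalization left 286 on their side of the threshold and ended 5 calls, quantile normalization left 279 and ended 6, and a floor of 0.2 ended 13 and one of 0.05 ended 23. Weights ended 34 and brought 40 past it, and leaving out 1 replicate ended 225 and left 353. Of gene list calls, 16 ended without the lowest 25% of genes by level, where lists were smaller, 3 with weights and 1 with median subtraction. The volumes of the weakest spots limit low genes, since ratios there end at the floor, and 2 replicates limit all. The cause of the changes listed next was not tested, except that leaving out a replicate or weak genes leaves fewer values and that other thresholds admit fewer or more genes by construction. For the counts past the score threshold, an exchange of series matrix and sample file values was not run, because the score is given in the series matrix and not in the sample files.

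Of the score, 3978 values lay at or past 2. At a threshold of 3 there were 1682: 7 under IPTG, 107 under chloramphenicol, 69 under erythromycin, 354 under hygromycin B, 40 under kanamycin, 115 under nalidixic acid, 31 under paromomycin, 91 under promethazine, 50 under puromycin, 45 under rifampicin, 204 under spectinomycin, 117 under streptomycin, 60 under sulfisoxazole, 115 under tetracycline, 161 under erythromycin with promethazine, 92 under paromomycin with rifampicin and 24 under paromomycin with streptomycin. Genes past it in a pair and not past it the same way in either component were also counted. The higher and lower ones then came to 62 and 88 for erythromycin with promethazine (128 and 206 at 2), 16 and 66 for paromomycin with rifampicin (83 and 138) and 7 and 15 for paromomycin with streptomycin (37 and 38). At a threshold of 1.5 there were 6935: 30 under IPTG, 538 under chloramphenicol, 239 under erythromycin, 1031 under hygromycin B, 171 under kanamycin, 509 under nalidixic acid, 166 under paromomycin, 338 under promethazine, 309 under puromycin, 281 under rifampicin, 669 under spectinomycin, 496 under streptomycin, 322 under sulfisoxazole, 477 under tetracycline, and 685, 482 and 192 under the pairs in the order above. With a robust z there were 8396: 324 under IPTG, 527 under chloramphenicol, 480 under erythromycin, 639 under hygromycin B, 493 under kanamycin, 519 under nalidixic acid, 413 under paromomycin, 437 under promethazine, 511 under puromycin, 490 under rifampicin, 622 under spectinomycin, 528 under streptomycin, 473 under sulfisoxazole, 524 under tetracycline, 551 under erythromycin with promethazine, 477 under paromomycin with rifampicin and 388 under paromomycin with streptomycin. Of the 324 under IPTG 198 were then lower, the split was 190 higher and 223 lower under paromomycin, and with median subtraction 67 and 190 under paromomycin with rifampicin.

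Limma made 2908 calls and per-treatment weights gave 4553, with 1696 in both. With weights there were 1 under IPTG, 77 under chloramphenicol, 61 under erythromycin, 1196 under hygromycin B, 46 under kanamycin, 366 under nalidixic acid, 17 under paromomycin, 271 under promethazine, 75 under puromycin, 138 under rifampicin, 578 under spectinomycin, 333 under streptomycin, 54 under sulfisoxazole, 375 under tetracycline, 632 under erythromycin with promethazine, 266 under paromomycin with rifampicin and 67 under paromomycin with streptomycin. With weights lacZ (3.79, adjusted p = 0.105) and lacY (3.21, adjusted p = 0.216) under IPTG did not pass. The contrasts of each pair with its first component, its second component and their sum gave 137, 505 and 52 for erythromycin with promethazine, 11, 60 and 1 for paromomycin with rifampicin, and 1, 79 and 14 for paromomycin with streptomycin. A floor of 0.2 gave 88 calls under IPTG and 10 under paromomycin with streptomycin, and a floor of 0.05 gave 306 and 10. Without the lowest 25% by level, 8 were called under nalidixic acid, 202 under erythromycin with promethazine and 11 under paromomycin with streptomycin. Median normalization gave 68 under streptomycin, and quantile normalization 55 there, 218 under erythromycin with promethazine and 12 under paromomycin with streptomycin. The correlation of erythromycin with promethazine and the sum of its components was 0.0868 by Spearman and 0.206 by Pearson. Within control membrane set 4 the difference in similarity between classes was 0.165 (exact permutation p = 0.114).

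Leaving out either replicate gave 394 to 725 calls under IPTG, 13 to 377 under chloramphenicol, 35 to 264 under erythromycin, 1 to 5 under hygromycin B, 50 to 149 under kanamycin, 3 to 6 under nalidixic acid, 69 to 1130 under paromomycin, 26 to 33 under promethazine, 9 to 53 under puromycin, 0 to 2 under rifampicin, 277 to 513 under spectinomycin, 10 to 112 under streptomycin, 24 to 82 under sulfisoxazole and 26 to 44 under tetracycline. It gave 85 to 134 under erythromycin with promethazine, 0 to 16 under paromomycin with rifampicin and 2 to 18 under paromomycin with streptomycin. Without replicate 1 the sign turned, and without replicate 2 it did not, for gph (0.00779 and -3.12) and murI (0.0699 and -2.66) under IPTG, nusB (0.61 and -1.21) under puromycin, and hisF (0.28 and -0.40) and ybdF (0.0114 and -0.0685) under paromomycin with streptomycin.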

Other observations

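The test of the hypothesis in the last paragraph below was chosen after the result was seen. Flagellar and chemotaxis genes passed camera downward in 12 treatments, and their median was below 0 in 15 of 17, although with an estimated correlation the smallest adjusted p was 0.454. Besides the drugs described above, the median log2 ratio was -0.20 under streptomycin (camera adjusted p = 5.1e-09, and 0.454 with an estimated correlation), with none of the 51 genes called by limma. It was -0.17 under nalidixic acid (adjusted p = 4.06e-07, and 0.506 with an estimated correlation) and -0.14 under promethazine, where 3 genes fell (adjusted p = 3.04e-06, and 0.565 with an estimated correlation). Aerobic respiration genes passed downward in 7 treatments, with medians of -0.31 under promethazine, -0.24 under rifampicin and -0.18 under kanamycin (smallest adjusted p with an estimated correlation, 0.208). Genes of tRNA synthetases, which charge tRNAs with amino acids, passed upward under erythromycin (median 0.23), hygromycin B (0.17) and spectinomycin (0.22, with 8 of 23 genes higher), and downward under promethazine (-0.21) and streptomycin (-0.15). With an estimated correlation their adjusted p was 0.354, 0.454, 0.467, 0.184 and 0.476. Methionine synthesis genes passed upward under kanamycin (0.16) and paromomycin (0.29, with 6 of 13 higher), with adjusted p of 0.264 and 0.237 with an estimated correlation.

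Several leader peptide genes of amino acid and nucleotide operons were among the lowest genes, a grouping noticed after their values were seen and not tested as a list. The tryptophanase leader tnaC fell under chloramphenicol (-1.24), hygromycin B (at least 4.03-fold) and tetracycline (at least 3.61-fold), pyrL under hygromycin B (-1.52) and sulfisoxazole (-1.32), leuL under the same drugs (-1.33 and -1.62), and ilvL under nalidixic acid (at least 2.18-fold). Some lists did not pass camera in any treatment: ribosome hibernation, OxyR regulon, phage shock, universal stress, purine synthesis, pyrimidine synthesis and folate metabolism, with 2, 0, 0, 2, 1, 1 and 2 of 17 treatments at an unadjusted p under 0.05.

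Drugs that raise heat shock genes may raise ribosomal protein genes less, a hypothesis formed from these data. Across the 9 translation inhibitors the medians of both lists correlated at r = -0.561 (exact permutation p = 0.119) and rho = -0.817 (exact permutation p = 0.0108, 362880 pairings), the only relation of this kind computed. Without kanamycin and paromomycin, the drugs farthest from the median in heat shock, r was -0.806, with median normalization -0.556, with quantile normalization -0.581, and on the score -0.670. The highest heat shock medians, under kanamycin (1.29), paromomycin (0.91) and streptomycin (0.41), were those of the single drugs with both controls in set 3. A part played by the set therefore cannot be told apart from this relation. Control membrane set 4 held only 4 of these drugs, too few for a value within it, so the test decides neither for nor against the hypothesis.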
